A study of Homo sapiens with 6 samples.

How the data were processed

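Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in SH-SY5Y cells, a human neuroblastoma line. Per the labels, 3 libraries came from cells with a control short hairpin RNA (shNC) and 3 from cells with a hairpin against TDP-43 (shTDP43), an RNA- and DNA-binding protein encoded by TARDBP. Per the labels' protocols the hairpins were delivered by lentivirus and stable knockdown cells were selected and kept in puromycin. The labels number the libraries 1 to 3 in each group and do not say whether these were separate cultures, so p-values measure the spread between these libraries, which may be technical.

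Reads were aligned to hg38 with tools that include Bowtie2 2.4.4 and SAMtools, per the submitters' processing notes. The handling of duplicate and multiply mapped reads, any Tn5 offset correction, the rule that set the regions and the counting tool are not given in the sources used here. The deposited table holds a signal value in each of 6 libraries for 39067 regions that the deposit's own name ties to transposable elements (TEs), and the authors' mean of each group. Its columns are called case and control, with a replicate number, and were matched to the library titles by those words. The rows carry coordinates and no TE name, subfamily or class. The header also names a log fold change for which the rows hold no value.

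Each deposited signal value is a whole number of reads multiplied by 1 constant per library: 100% of the values of every library were whole multiples of that library's smallest value, within 1e-06. The constants were 0.984, 0.972 and 0.823 for shNC replicates 1 to 3 and 0.928, 1 and 0.990 for shTDP43 replicates 1 to 3. What they were computed from is not given in the sources used here. Dividing by them recovered 727258, 732140 and 882701 reads for shNC and 867175, 807689 and 1058863 for shTDP43, which are reads in the listed regions and not the sequencing depth. The median region held 9 to 15 reads per library, so single regions were measured coarsely. The smallest mean value of a row was 5.00, so regions of lower mean signal are not in the table. Replicate pairs of a group differed by more than counting noise, with chi-square per degree of freedom from 1.82 to 2.58, so each library was counted once. Counting intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

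The design fixed before the data were examined foresaw either counts or normalized values. Because the unit was a signal, the test for normalized values was used. It was limma 3.58.1 in R 4.3.3 on log2(value + 1), with a variance trend and robust moderation, group as the only term, all 39067 regions tested, Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of regions with low values. Standard errors (SE) are limma's. The median log2 fold change of all regions was 0.34 on the deposited scale and 0.01 with edgeR 4.0.16, TMM scaling and the quasi-likelihood test on the recovered reads, an alternative added after the data were seen. Values from that test are given beside those of limma as TMM values. Other alternatives were pseudocounts of 0.1 and 5, median centring, quantile normalization, no variance trend, the upper 50% of regions by mean, the replicate number as a block, stricter thresholds, each library left out in turn and, added after the data were seen, other scalings of the recovered reads, DESeq2 1.42.0 and voom. DESeq2 ran with its default filter, which gives regions of low mean no adjusted p, and such regions count as not called by it.

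Coordinates are 1-based hg38. Gene names came from NCBI RefSeq gene spans of the GRCh38 assembly. That table gives no exons, so whether a region is exonic or intronic is not stated. Of the regions, 47.1% overlapped a protein-coding gene, 13.5% another annotated gene and 39.4% no gene. Regions named here follow a rule fixed before the data were examined: the 12 higher and the 12 lower regions with the smallest p among those with adjusted p under 0.05 and no overlap between the groups, and the regions of lowest and highest fold in each fixed gene list. The regions of TARDBP are given as those of the targeted gene. Other regions named within the lists, and all those named only in the closing part, were chosen after their values were seen. The 7 gene lists, like the rule, were fixed beforehand. A region was linked to a list gene when it lay within 10 kb of the gene's span, a distance chosen after the files were seen, with 0 and 50 kb as alternatives. Lists were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 7 lists, and with an estimated correlation and fry as alternatives. Library totals and list medians per library were compared by two-sided exact permutation tests, for which 3 against 3 cannot give a p below 0.1. These used SciPy 1.17.1 in Python 3.11.15.

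The planned tests of TE subfamilies and classes, including 18 TE lists, were not run because the rows name no element. The authors' own comparison was not described because its column holds no values. On simulated reads for the comparison of shTDP43 with shNC, drawn for the same 39067 regions with 200 changed, limma recovered 13% of 2-fold and 41% of 4-fold changes with 1 call among unchanged regions, and edgeR with TMM scaling recovered 12% and 42% with 3 such calls. With all regions also raised by 0.34 on the log2 scale, the median shift of the real values, limma made 156 calls, 150 of them higher, and 81 were among regions that had only this shift. edgeR with TMM scaling then made 62 calls, 1 of them among such regions. With a list shifted by 0.5, camera gave it a p of 6.7e-10 and called none of the 6 lists left unshifted. The simulated regions were drawn independently of each other, while the real adrenergic list had an estimated correlation of 0.16. This run therefore cannot show how camera at the preset correlation behaves on the real regions.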

Results

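The data described chromatin accessibility at 39067 genomic regions tied to transposable elements in SH-SY5Y neuroblastoma cells, with 3 libraries from control cells (shNC) and 3 from cells with stable knockdown of TDP-43 (shTDP43). Regions had a median width of 220 bp, and the widest spanned 13136 bp. Between 727258 and 1058863 reads per library fell in them. The series asked how loss of TDP-43 alters transposable elements, and the comparison of shTDP43 with shNC addressed where their chromatin became more or less open.

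The targeted gene, TARDBP, had 2 linked regions on chromosome 1. The region at 11011991–11012127, 0.527 kb outside the gene, had 10.4 ± 0.966 scaled reads in shTDP43 and 6.27 ± 2.4 in shNC (SD, n = 3 each, limma adjusted p = 0.507). The region at 11013213–11013515, inside the gene, had 12.2 ± 2.97 and 11.7 ± 0.910 (adjusted p = 0.974). Accessibility does not measure the transcript that a hairpin targets, so these values do not test the knockdown.

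On the deposited scale, more regions gained than lost accessibility in shTDP43. limma called 1837 regions, of which 1562 were higher and 275 lower in shTDP43. The groups did not overlap in 1491 of the higher and 255 of the lower calls. Over all regions, the 3 shTDP43 values lay above all shNC values in 19.7% and below them in 3.51%, where chance gives 10% for both directions together. The scaled totals were 804315 to 1048320 in shTDP43 and 711314 to 726742 in shNC, a ratio of means of 1.24 (exact permutation p = 0.1, the smallest that 3 against 3 allows). shTDP43 replicate 3 had the highest total, and the ratio was 1.12 without it. The split between higher and lower calls moved with the scaling. After TMM scaling of the recovered reads, edgeR called 893 regions, 314 higher and 579 lower, and 294 of the 1562 higher and 264 of the 275 lower calls were kept. TMM scaling moved the median log2 fold change of all regions from 0.34 to 0.01, which by itself keeps falls more easily than rises. Median centring gave 436 higher and 485 lower, and without a variance trend limma called 0 regions, although 4862 were higher and 917 lower at an unadjusted p under 0.05. Without shTDP43 replicate 3 the calls were 434 higher and 295 lower. Leaving out shNC replicate 2, shTDP43 replicate 1 or shTDP43 replicate 2 left 1204, 1103 and 1128 calls, and leaving out any library but shTDP43 replicate 3 brought the lower calls to between 121 and 169.

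**Figure D1:**
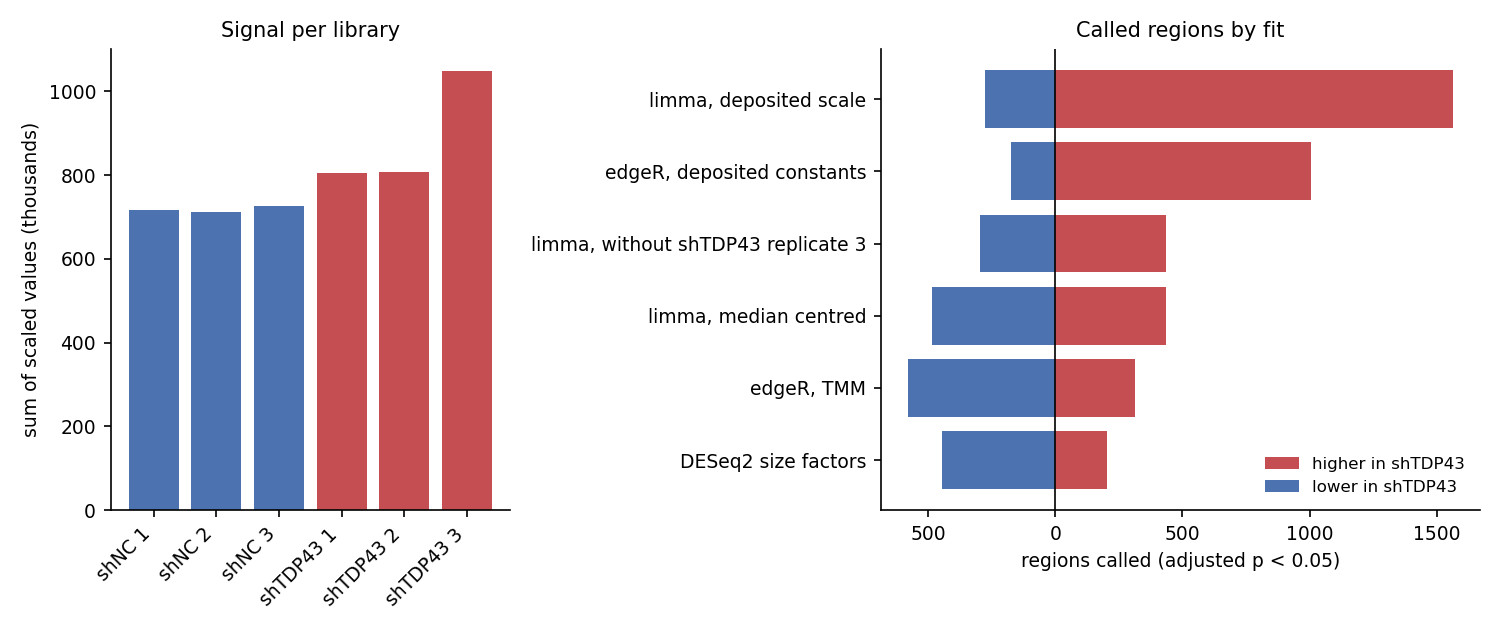
Left, the sum of scaled values over 39067 regions in each library, in units of 1000, with shNC in blue and shTDP43 in red. Right, the number of regions called higher (red, to the right of 0) and lower (blue, to the left of 0) in shTDP43 at an adjusted p under 0.05 by 6 fits; the deposited scale gives 1562 higher and 275 lower, and TMM scaling gives 314 and 579.

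Of the 12 named higher regions, 10 lay inside annotated genes, 3 of them uncharacterized, and 11 of the 12 also passed with TMM scaling. A region of 2009 bp in the uncharacterized gene LOC105371703 (chromosome 17, 27088524–27090532) rose from 115 ± 6.79 scaled reads in shNC to 359 ± 36.4 in shTDP43 (SD, n = 3 each), a log2 fold change of 1.63 ± 0.15 (SE, limma adjusted p = 3.1e-18, TMM 1.34). In HDAC9, which encodes a class IIa histone deacetylase, the region at chromosome 7, 18821562–18822326 rose from 136 ± 6.70 to 347 ± 12.2 (log2 fold change 1.34 ± 0.14, adjusted p = 9.7e-14, TMM 1.03). The rise with the highest fold among the 12 was in TMEM178A, a transmembrane protein gene (chromosome 2, 39729029–39729471), from 20.3 ± 13.3 to 133 ± 19.7 (log2 fold change 2.81 ± 0.28, TMM 2.39). STXBP5-AS1, an antisense RNA gene, held a region (chromosome 6, 146974882–146975345) that rose from 15.8 ± 6.78 to 92.3 ± 12.5 (log2 fold change 2.56 ± 0.30). Regions in PPP1R16B, a regulatory subunit of protein phosphatase 1, in FNIP2, a folliculin-interacting protein, in CPNE4, a copine, and in PKHD1, the fibrocystin gene, rose by log2 fold changes of 1.82, 1.32, 2.06 and 1.84. The other named rises were in LOC107985122 (2.39) and LOC105371632 (1.98), in an intergenic region of chromosome 13 at 105272980–105274410 (1.25), and 32.9 kb from DLK1, a Notch-related ligand gene. That last region (chromosome 14, 100771098–100771609) rose by 0.84 ± 0.10 on the deposited scale, from 366 ± 30.9 to 656 ± 56.4 scaled reads, but its TMM value of 0.52 did not pass (edgeR adjusted p = 0.061).

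The 12 named lower regions all passed with TMM scaling as well. That scaling moved the median log2 fold change of all regions from 0.34 to 0.01, so falls pass it more easily than rises. A region of 1710 bp in the mucin gene MUC22 (chromosome 6, 31020539–31022248) fell from 187 ± 24.2 scaled reads to 40.7 ± 7.97 (SD, n = 3 each), a log2 fold change of -2.19 ± 0.21 (SE, limma adjusted p = 2.0e-16, TMM -2.54). An intergenic region of 60 bp on chromosome 4 (147054729–147054788) fell from 69.3 ± 11.5 to 7.85 ± 7.79 (log2 fold change -3.32 ± 0.39). In DPYSL3, which encodes a protein of neuronal growth cones, the region at chromosome 5, 147474375–147474581 fell from 157 ± 28.8 to 62.4 ± 2.16 (log2 fold change -1.30 ± 0.20). NRG1, which encodes a ligand of ErbB receptors, held a region (chromosome 8, 31779679–31779817) that fell from 111 ± 16.9 to 38.6 ± 15.7 (log2 fold change -1.55 ± 0.24). A region 10.6 kb from BCL2, the anti-apoptotic gene, fell from 119 ± 11 to 45.4 ± 6.42 (chromosome 18, 63112202–63112774, log2 fold change -1.37 ± 0.23). ASCC2, a subunit gene of the activating signal cointegrator complex, held a region at chromosome 22, 29830793–29830897 that fell from 41.8 ± 6.70 to 6.85 ± 1.92 (log2 fold change -2.47 ± 0.41). The other named falls were in CFDP1 (-1.62), PARM1 (-1.42), LOC101928277 (-1.85) and LOC105376988 (-2.89), and between genes on chromosome 15 at 70154852–70155384 (-1.21) and chromosome 3 at 118347826–118348222 (-2.07).

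Regions at adrenergic neuroblastoma genes, the genes that mark the noradrenergic identity of such cells, had higher log2 fold changes as a list than the remaining regions by camera (adjusted p = 1.3e-07). The call was lost with an estimated correlation (adjusted p = 0.685). It was weaker with 1 mean value per gene, a setting added after the data were seen (camera at the preset correlation, adjusted p = 0.012). Of the 67 regions, linked to 13 of the 16 genes, 52 lay above the median of all regions. Of the 67, 14 were called higher and 0 lower by limma, where 30 and 0 had an unadjusted p under 0.05. With p-values adjusted over the list alone, 23 were called higher. edgeR with TMM scaling called 9 higher and 0 lower, and DESeq2 and voom each called 8 higher and 0 lower. The list's median log2 fold change was 0.82 against 0.34 for all regions, and 0.60 against 0.01 with TMM scaling. In each library, the list's median relative to that of all regions was 0.60 ± 0.07 in shTDP43 and -0.18 ± 0.09 in shNC on the log2 scale, with no overlap (SD, n = 3 each, exact permutation p = 0.1, adjusted 0.7 over 7 lists).

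Of the 14 adrenergic regions called by limma, 5 were linked to CHGA, 4 to DBH and 3 to DDC. Not all of these passed with TMM scaling. Of the 6 regions that overlap CHGA, limma called 4 higher and edgeR with TMM scaling called 2. The called DDC region at chromosome 7, 50508652–50508730 (log2 fold change 0.61) had a TMM value of 0.27 and did not pass (edgeR adjusted p = 0.461). Apart from the list's lowest and largest folds, the regions named for it were chosen after their values were seen. CHGA, which encodes chromogranin A of secretory granules, had 14 regions with 5 called higher and a mean log2 fold change of 1.77 ± 0.41 (SE). Its region at chromosome 14, 92934626–92934721 rose from 13.2 ± 4.35 scaled reads to 45.9 ± 5.01 (SD, n = 3 each, limma adjusted p = 3.0e-04, TMM 1.45). The list's largest fold was at the CHGA region 92925716–92925862, with 42 reads in the 3 shTDP43 libraries and 3 in the 3 shNC libraries, a ratio of 14.8 with an exact 95% counting interval from 4.72 to 74.5. Another called region, at 92936023–92936281, lay 738 bp from CHGA and closer, at 633 bp, to ITPK1. DBH, which encodes the enzyme that makes noradrenaline from dopamine, had 12 regions with 4 called higher and a mean of 1.25 ± 0.34. Its region 9.12 kb from the gene at chromosome 9, 133626891–133627247 rose from 21.8 ± 5.37 to 94.2 ± 15.2 (log2 fold change 2.08 ± 0.28, adjusted p = 2.6e-09, TMM 1.79). The called region at 133667516–133667666 lay 8187 bp from DBH and inside SARDH, the sarcosine dehydrogenase gene. DDC, the dopa decarboxylase gene, had 10 regions with 3 called higher and a mean of 0.99 ± 0.30. Its region at chromosome 7, 50567856–50568032, 2.45 kb from the gene, rose from 68.0 ± 10.3 to 165 ± 25.1 (adjusted p = 4.4e-07, TMM 0.94). Single regions linked to the transcription factor genes GATA2 (log2 fold change 0.93, 8958 bp away and inside DNAJB8-AS1) and HAND1 (1.97) were called on the deposited scale and did not pass with TMM scaling (edgeR adjusted p of 0.063 and 0.067). No region of PHOX2A, HAND2, GATA3, TBX2, KLF7, CHGB or DLK1 within 10 kb passed, and the means of PHOX2A (-0.08) and HAND2 (0.18) lay under the 0.34 of all regions. The list's lowest fold was at a region inside INPPL1 and 7142 bp from PHOX2A (-0.62, adjusted p = 0.510).

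**Figure D2:**
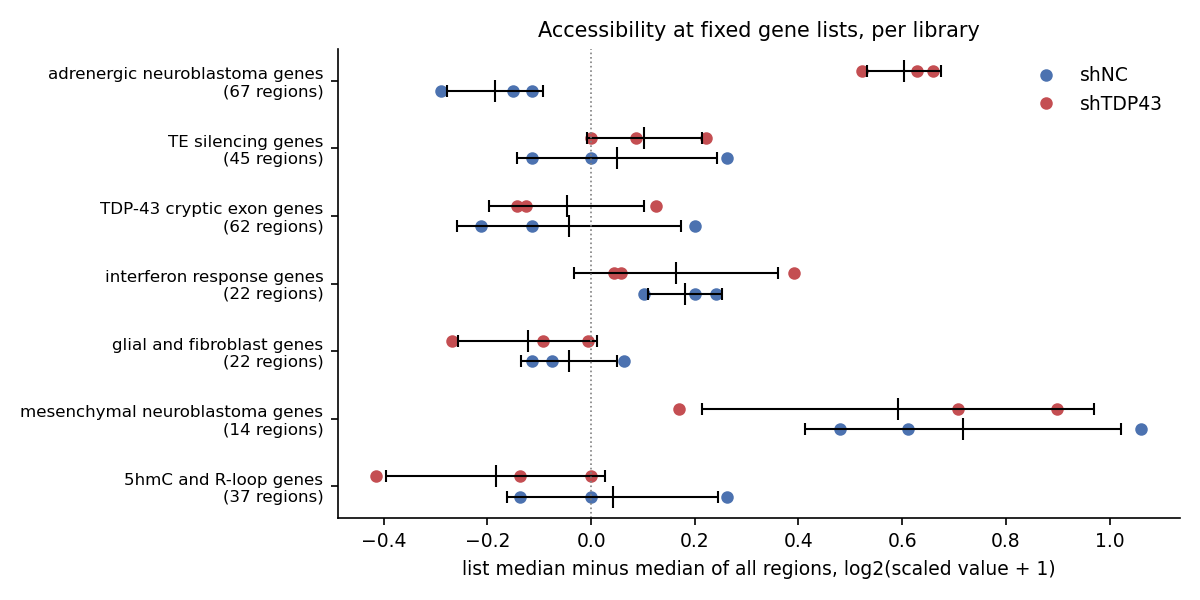
Median log2(scaled value + 1) of the regions of each of 7 gene lists, minus the median of all regions, in each library (points, shNC blue and shTDP43 red), with the mean (tick) and SD (bar) of 3 libraries. The adrenergic list lies at 0.60 ± 0.07 in shTDP43 and -0.18 ± 0.09 in shNC, and the groups overlap in the other 6 lists.

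**Figure D3:**
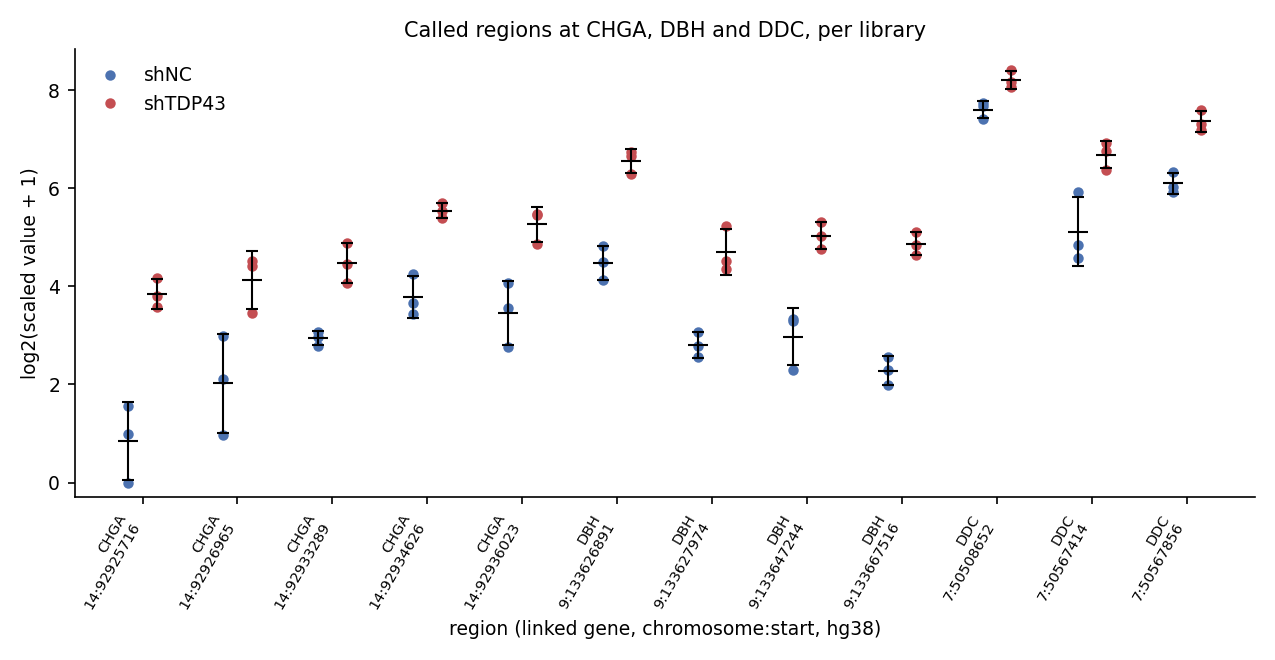
The 12 regions linked to CHGA, DBH and DDC that limma called on the deposited scale, not all of which passed with TMM scaling. They are named by gene, chromosome and start on hg38, with log2(scaled value + 1) on the vertical axis. Each library has a point (shNC blue, shTDP43 red), with the mean (tick) and SD (bar) of 3 libraries. At each region the 3 shTDP43 libraries lie above the 3 shNC libraries.

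The other 6 lists did not differ from the remaining regions by camera, with adjusted p from 0.604 to 0.865. camera's direction differed from that of the list's median against the 0.34 of all regions for the targets of TDP-43 splicing repression (lower, median 0.42) and the mesenchymal markers (higher, median 0.27). TE silencing genes had 45 regions at 18 genes. limma called 2 of them higher, in the DNA methyltransferase genes DNMT3A (log2 fold change 1.53) and DNMT1 (0.48), and neither passed with TMM scaling (adjusted p of 0.169 and 0.748). voom called 1 region lower. The list's lowest fold was in DNMT3A as well, at chromosome 2, 25307006–25307069 (-1.31, adjusted p = 0.125). Known targets of TDP-43 splicing repression had 62 regions at 16 genes, with 3 called higher by limma, in CAMK2B (0.74), HDGFL2 (2.22) and UNC13A (1.47), and 1 lower, in KALRN (-1.68). With TMM scaling, which falls pass more easily than rises, the KALRN call held (edgeR adjusted p = 0.034) and the 3 rises did not pass. Genes of 5-hydroxymethylcytosine and R-loop handling had 37 regions at 20 genes, and the 1 limma call was a fall at chromosome 14, 20466983–20467146, 9216 bp from APEX1 and 2.26 kb from PNP, from 20.4 ± 9.24 scaled reads to 3.65 ± 3.20 (SD, n = 3 each, limma adjusted p = 0.0022). edgeR with TMM scaling and DESeq2 each called 2 regions lower and voom called 1. The second edgeR call was in TOP1, the topoisomerase I gene (chromosome 20, 41058251–41058749), with 73.5 ± 15.2 scaled reads in shTDP43 and 108 ± 11.9 in shNC, no overlap, a TMM value of -0.91 (adjusted p = 0.0071) and a limma value of -0.56 (adjusted p = 0.10). The TOP1 region, and the called regions of DNMT1, CAMK2B, UNC13A and ID1, were named after their values were seen. The list's largest fold, 6.39 kb from TET1, had a log2 fold change of 1.97 and did not pass (adjusted p = 0.362).

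Interferon response genes had 22 regions at 10 genes, with 0 called by limma, edgeR or DESeq2, 1 called lower by voom and 3 at an unadjusted limma p under 0.05. Their folds ran from -0.53 near ISG15 to 1.29 near ZBP1. Markers of the mesenchymal or substrate-adherent state that neuroblastoma lines can hold had 14 regions at 8 genes, with 1 called higher, 8740 bp from ID1 (log2 fold change 0.71, TMM adjusted p = 0.469). Near FOSL1, a region at chromosome 11, 65902058–65902270 had no reads in the 3 shNC libraries and 11.4 ± 2.32 scaled reads in shTDP43 (SD, n = 3). The shTDP43 mean was 12.3-fold higher than a floor of 3 counts over the shNC group. That fold leaves out the counting error of the shTDP43 mean, so it is not a lower limit. limma did not call it (adjusted p = 0.203) and edgeR with TMM scaling did (adjusted p = 0.0070). The list's lowest fold was in COL1A1 (-1.06, adjusted p = 0.446). Glial and fibroblast markers had 22 regions at 6 genes, 14 of them linked to PDGFRB. Of the 22, 0 were called by limma, edgeR, DESeq2 or voom and 0 had an unadjusted limma p under 0.05. Their folds ran from -1.23 near DCN to 1.55 at a region inside CSF1R and 1441 bp from PDGFRB.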

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

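Settings that use the recovered reads, other link distances or other list units, and regions that overlap no other, were chosen after the data were seen. Among limma fits on the deposited scale, pseudocounts, the upper 50% of regions, fold thresholds and regions that overlap no other kept all 3 counts within 1.5 times of 1837 calls, 1562 higher and 275 lower. An adjusted p under 0.01 left 737, 626 and 111, because the threshold is stricter, and no variance trend left 0, 0 and 0 (4862 higher and 917 lower at an unadjusted p under 0.05). Centring in limma changed the balance by construction: total, higher and lower calls were 921, 436 and 485 with median centring and 1311, 586 and 725 with quantile normalization. edgeR gave 1179, 1005 and 174 with the deposited constants, and the cause of the difference from limma was not tested. Within edgeR, rescaling gave 893, 314 and 579 with TMM, 867, 404 and 463 with upper quartiles and 929, 387 and 542 with plain totals. DESeq2 (650, 204 and 446) and voom (1014, 329 and 685) changed both the tool and the scaling, and the cause was not tested. Leaving out 1 library gave 729 to 1415 calls, 434 to 1263 higher and 121 to 295 lower, with fewer samples. The lowest total and lowest higher count came without shTDP43 replicate 3. The total signal ratio ran from 1.12 to 1.29, and was 1.17 for recovered reads. All 24 named regions kept their direction in every refit that tested them, and 3 settings ended calls: no variance trend ended all 24, and both TMM without the block and a log2 fold threshold of 1 ended the one near DLK1 (the ASCC2 region overlaps another and was not among regions that overlap no other).

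No pairing of the libraries by replicate number was seen: deviations of same-numbered libraries correlated at 0.008, 0.005 and 0.016. Counting noise at single regions lowers such correlations, so a weak pairing is not excluded. With a replicate block limma called 2163, 1841 higher and 322 lower, and edgeR with TMM and the replicate block called 838, 292 and 546. The adrenergic list gave an adjusted p of 6.1e-07 with the replicate block.

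The adrenergic list passed with camera at the preset correlation in every setting run (adjusted p from 4.1e-08 to 0.012) and not with an estimated correlation (0.685), and leaving out 1 library gave 1.7e-07 to 1.9e-06. The weakest, 0.012, came with 1 mean value per gene, which takes away the weight of genes with many regions. Adjusted p without 1 library ran from 0.692 to 0.992 for TE silencing, 0.406 to 0.826 for 5hmC and R-loop, 0.657 to 0.992 for cryptic exon, 0.690 to 0.998 for interferon, 0.593 to 0.992 for mesenchymal and 0.594 to 0.843 for glial and fibroblast genes. None of these passed, and directions turned in some. fry, which does not compare a list with other regions, called adrenergic, interferon and mesenchymal genes higher (adjusted p = 0.021 each) and turned the direction of 5hmC (0.336) and cryptic exon genes (0.166). Links of 50 kb turned 5hmC (0.959) and mesenchymal genes (0.898), and gene bodies alone turned interferon and mesenchymal genes (0.771 each), and the cause was not tested. The uncalled PHOX2A region (-0.62) turned to 0.13 without shTDP43 replicate 1, the other end of a range from -1.28. Not run were all alternatives on TE subfamilies, classes and TE lists, unique against multiply mapped reads, peak overlap and the authors' thresholds. Dropping rows of zeros removed none. Depth limits the rest: the 7814 regions of mean signal up to 6.22 held 0 limma, DESeq2 and voom calls, against 21 by edgeR and 328 at an unadjusted limma p under 0.05. The 0 of DESeq2 may stand for regions that its default filter left without an adjusted p.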

Other observations

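The genes and regions named outside the fixed lists, TMM scaling, the comparisons by neighbour and length, and the bounds of all tests of an explanation were chosen or last set after the values were seen, while the limma calls, those without shTDP43 replicate 3 and the camera test of each list were planned. The genes outside the lists with most regions called higher by limma were CAMTA1, with 7 of 46, and DISC1, with 7 of 22, or 7 of 27 in the readthrough gene TSNAX-DISC1 that spans it. Over all regions limma called 1562 of 39067 higher. The median log2 fold change was 0.13 in CAMTA1, under the 0.34 of all regions, and 0.84 in DISC1. With TMM scaling edgeR called 1 higher and 1 lower in CAMTA1, none higher and 1 lower in DISC1, and 2 lower in TSNAX-DISC1. In some other genes called regions passed with both. In CD38, which encodes an enzyme that consumes NAD, 5 of 6 regions in 15793230–15794741 on chromosome 4 were called higher, with a median log2 fold change of 1.73 (TMM 1.40, 2 called). In ICA1, 3 of 13 regions on chromosome 7 were called higher, the strongest with a log2 fold change of 2.35 ± 0.38 (SE), and edgeR with TMM scaling also called 3. In PCGF5, a gene of Polycomb repressive complexes, 3 of 5 regions were called higher by limma and by edgeR with TMM scaling, at log2 fold changes of 2.23 to 2.52 on chromosome 10.

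Some genes held several falls. In ASCC2 all 4 regions in 29830354–29831192 of chromosome 22 were lower by both limma and TMM scaling, with a median log2 fold change of -2.31. Some of these regions overlap and share reads. In TMEM156 all 3 regions were lower by both (median -1.27), and in PCBP3 3 of 24 were lower by limma and 4 with TMM scaling. SCRG1, which lies within 200 kb of the adrenergic gene HAND2, had 4 of 8 regions lower by both. Within 200 kb of HAND1, 6 of 29 regions were higher by limma, and 1 by edgeR with TMM scaling. The difference between the HAND1 and HAND2 surroundings was not tested.

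Changes were shared between close neighbours. The log2 difference of shTDP43 replicate 1 from shNC replicate 1 at a region was set against that of shTDP43 replicate 2 from shNC replicate 2 at another, so that no library entered both sides. Across pairs of regions, which are not independent replicates, the correlation was 0.22 for 9255 pairs up to 1 kb apart, 0.07 from there to 10 kb, 0.03 to 100 kb and 0.004 to 1000 kb. For a region with itself it was 0.20. The pairs up to 1 kb apart include 725 that directly abut, so part of the 0.22 may compare adjoining pieces of the same open stretch. Regions of over 5900 and up to 6300 bp, a band that holds the length of a full LINE-1 element, had a median log2 fold change of 0.15 (742 regions) against 0.34 for the others. Per library, the band's median relative to other regions ran from -0.51 to -0.29 in shNC and from -0.68 to -0.41 in shTDP43 (exact permutation p = 0.4), so the libraries did not separate by group.

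Of the calls on the deposited scale 85.0% were higher, and 35.2% with TMM scaling, but TMM itself brings the median log2 fold change of all regions from 0.34 to 0.01, so this cannot tell scaling from a shift of all regions, and scaling stays open. In shTDP43 replicate 3 the ratio to the shNC mean was 1.62 over the sparser 50% of regions by reads per kb and 1.31 over the densest 10%, a difference of 0.31, while the other 5 libraries differed by at most 0.05 in size, which is consistent with more background reads in that library. That library alone as the source stays open: without it 59.5% of calls were higher, yet the other shTDP43 libraries kept a total 1.12 times the shNC mean, where single shNC libraries reached 1.01. Only 1 of the 10 splits of the 6 libraries gave as many calls (1837, highest other 0, with at most 1667 at an unadjusted limma p under 0.05), and 10 splits are too few for a share under 0.05. A wider opening of TE chromatin by loss of TDP-43, the biological difference the design names, also stays open, as untested.

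The adrenergic list's median lay 0.59 above that of all regions with TMM scaling as well. A scaling constant per library moves all regions nearly alike and so largely cancels in this difference. The value is therefore no test of scaling, which by construction could hardly set the list apart from other regions. Of the 12 genes other than CHGA, 10 had a mean above the median of all regions, which argues against that gene alone, and without it camera at the preset correlation gave an adjusted p of 5.2e-04, although an estimated correlation ends the call of the full list (adjusted p = 0.685). Regions 100 kb to 2 Mb away differed in TMM median from all regions by 0.18 at CHGA (upper bound 0.30, the gene's own list regions 1.55). At DBH they differed by -0.10 (upper bound 0.011, own 0.83). These values argue against a gain reaching that far as the source of most of the rise at CHGA and DBH, with 5 and 4 of the 14 calls. A smaller gain at CHGA is not excluded, and the bounds at single genes resampled regions as if they were independent. At DDC (0.16, upper bound 0.62, own 0.46) and over the 990 such regions of all list genes (-0.0076, upper bound over genes 0.16) a gain of some segments is not excluded, nor is one shorter than 100 kb at any gene. Only 1 of 10 splits gave a -log10 p as large (7.72, highest other 2.06), too few splits for a share under 0.05, and an effect of TDP-43 or the outgrowth of some cells under selection may each give these values and stay open, as does a shift in cell state, for which the mesenchymal list did not pass (camera adjusted p = 0.835).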
